A study of Homo sapiens and Bos taurus with 12 samples.

How the data were processed

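Messenger RNA was sequenced from 12 libraries of endometrial stromal fibroblasts, the connective tissue cells of the uterine lining that trophoblasts of the placenta meet at implantation. The design text of the series names stromal trophoblasts, whereas each sample's source and cell type name stromal fibroblasts, which was taken as the cell type. The labels gave 4 groups of 3 libraries each: human cells alone, human cells co-cultured with human trophoblasts, bovine cells alone and bovine cells co-cultured with bovine trophoblasts. Per the labels' protocols, poly(A) libraries were made with an Illumina TruSeq kit and read single-end on a HiSeq instrument. The growth protocol described human cells only, and the conditions of the bovine cultures, the trophoblast cells used, the length of co-culture and any step that parted stromal cells from trophoblasts were not given in the sources used here. Table columns whose names carried "Mix" were taken as the co-cultured libraries.

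The deposited values were TPM (transcripts per 1000000), made by the authors. Per the submitters' processing notes, the tools were STAR and Partek and the genome builds hg38, bosTau8 and UMD3.1, whereas aligner settings, quantification and annotation versions were not given in the sources used here. From the values, the deposited table had 23031 rows keyed by 19779 human Ensembl gene identifiers, of which 1299 had more than 1 row. Every column of deposited TPM summed to 1000000 over all rows, repeats included, so a library's values depend on that row set. TPM keeps no sequencing depth, so the number of reads behind any value is unknown and no counting interval or detection floor is given. A TPM also rests on annotated transcript lengths, which differ between the genome annotations of the 2 species.

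One value per identifier was kept for the human libraries. Each distinct bovine row was kept for the bovine libraries. Comparisons between species used the 13402 genes with 1 human identifier, 1 bovine row and a value above 0 in each species, with TPM rescaled to 1000000 per library over these genes. In total 26 symbols that had turned into bare numbers were replaced through the identifier with those of GENCODE 29, which names 19719 of the identifiers. Human coordinates are those of GENCODE 29 on GRCh38, the assembly that hg38 denotes. No bovine annotation was used here, so bovine positions are not given. XIST and Y-linked genes, 42 identifiers, were left out throughout.

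Before the data were examined, the comparisons, tests, gene lists, alternatives and the rule for named genes were fixed. Genes with at least 1 TPM in 3 or more of the libraries in a fit were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend, two-sided, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05). Fold changes are on that log2(TPM + 1) scale, which understates the change of low genes. Each within-species response was fitted on the 6 libraries of that species. The difference of the responses (the interaction of species and co-culture) and both species differences came from 1 fit of all 12 libraries. No result had a covariate. The labels do not say that replicates came from separate cultures, animals or donors, so p-values measure only the spread between these libraries, which may be technical.

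A total of 27 gene lists were compared with all other tested genes by camera (limma) with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists that had 5 or more tested genes. They covered matrix, adhesion and contractile genes, signalling pathways, metabolism, markers of stromal and other cell types, and mitochondrial and ribosomal genes as checks. All were written from general knowledge. An alternative estimated the correlation per list, and camera then also takes its degrees of freedom from the few libraries rather than from the genes. A call lost under it therefore need not mean correlated genes. Human interferon-stimulated genes had an estimated correlation of -0.0011, below the preset, yet went from camera adjusted p = 0.0047 to 0.465. For other lists the estimate was above the preset, as with human trophoblast markers at 0.568. Counts of list members past the threshold are over all genes tested, with the count adjusted over the list alone where the counts differ.

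The rule for named genes took the 6 that rose and the 6 that fell most in each response and in the difference of responses, and 8 in each direction for the species difference without trophoblasts. Such a gene had to pass the threshold, reach a mean of 5 TPM in the higher group and, except for the difference of responses, show no overlap between groups. Up to 3 members were added from each list called by camera or with 3 or more members past the threshold. Markers of other cell types could be named with their values.

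The code was tested on simulated log2 TPM for the real genes with 200 changed genes per comparison. At a log2 change of 1, limma recovered 89% of them for the human response, 87% for the bovine response, 78% for the difference of responses, 94% for the species difference alone and 97% for that in co-culture. At 0.5 it recovered 54%, 44%, 22%, 62% and 53% in the same order. False calls were between 1.38% and 7.98% of those made, the highest for the species difference in co-culture. The simulation used independent noise and few changed genes. Its shares therefore do not carry over to the real comparisons, in which most genes passed.

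Alternatives covered the pseudocount (0.1 and 5), the filter (none, or a mean of at least 5 TPM), scaling (median of ratios, quantile normalization, totals without mitochondrial and ribosomal protein genes, TPM as deposited), the empirical Bayes options, each replicate left out, a replicate block and stricter thresholds. Added after the data were seen were a filter of a mean of 1 TPM in each species and list tests without 1 human library. Replicates of a group correlated at Pearson's r of 0.983 to 0.997 across genes, and no pair held identical values. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.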

Results

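The series compared endometrial stromal fibroblasts of human and cow with and without co-culture with trophoblasts of the same species, and its title places the comparison in the context of how far a placenta invades. Human placentas invade the uterine stroma deeply, whereas those of cattle hardly invade it. There were 3 libraries in each of 4 groups. Between 11000 and 11763 genes reached 1 TPM in a human library and between 11471 and 11713 in a bovine one. The read depth behind these TPM values is unknown. Values are means ± SD over 3 libraries unless stated, and log2 changes are given ± SE from limma.

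The first question was how the human stromal cultures changed with trophoblasts. By median, epithelial and trophoblast markers rose most of the gene lists. PGF, placental growth factor, went from 3.73 ± 5.04 TPM alone to 299 ± 44.1 TPM in co-culture (log2 change 6.51 ± 0.60, adjusted p = 2.4e-05). CGA, the common alpha subunit of chorionic gonadotropin and other glycoprotein hormones, went from 2.57 ± 2.58 to 225 ± 32.1 TPM (6.20 ± 0.40, adjusted p = 4.0e-06). NLRP2, CPVL, LCP1 and RAB11FIP4 completed the 6 that rose most, with NLRP2 at 1592 ± 67.1 TPM in co-culture. Their values alone were raised by 1 of the 3 human libraries without trophoblasts, and without it the log2 changes were 7.35 for PGF, 7.78 for NLRP2, 7.39 for CPVL, 7.22 for LCP1, 7.13 for RAB11FIP4 and 6.75 for CGA. The 6 that fell most were FOSL1, an AP-1 transcription factor (216 ± 31.2 to 17.6 ± 1.91 TPM, log2 change -3.54 ± 0.12, adjusted p = 9.4e-07), BMPER, a BMP-binding secreted protein (50.3 ± 1.83 to 3.72 ± 0.21 TPM), SERPINB2, an inhibitor of plasminogen activators, the growth factor FGF5 (108 ± 9.22 to 9.83 ± 0.33 TPM), the receptor EPHB1 and PTX3. On GRCh38, PGF (ENSG00000119630) lies on chromosome 14 from 74941834 to 74955784, CGA (ENSG00000135346) on chromosome 6 from 87085498 to 87095406, FOSL1 (ENSG00000175592) on chromosome 11 from 65892049 to 65900573 and BMPER (ENSG00000164619) on chromosome 7 from 33904308 to 34156356. All 4 are annotated as protein-coding genes.

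Of the 23 tested trophoblast markers, 20 rose and 2 fell in human co-culture, with a median log2 change of 3.46 (camera adjusted p = 2.7e-05; adjusted p = 0.465 with an estimated correlation). CYP19A1, the aromatase of placental oestrogen synthesis, went from 0.80 ± 1.08 to 95.6 ± 11.8 TPM and GATA3, a trophoblast transcription factor, from 5.49 ± 7.51 to 208 ± 15.6 TPM. Epithelial markers moved with them, 16 of 18 rising and none falling (median 4.47, adjusted p = 6.5e-05; adjusted p = 0.465 with an estimated correlation). Among these, the adhesion protein CDH1 went from 10.7 ± 15.8 to 336 ± 22.4 TPM. The SD alone is large because that same library held these transcripts at a low level. Of the 272 genes that rose over 8-fold against the other 2 libraries and reached 20 TPM, 271 were higher in this library than in both. The log2 changes were 5.67 for GATA3 and 5.83 for CDH1, and without that library 6.61 and 7.00, while 17 epithelial markers rose with a median of 5.08. Without it 8822 genes changed, against 8469 with all libraries.

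**Figure D1:**
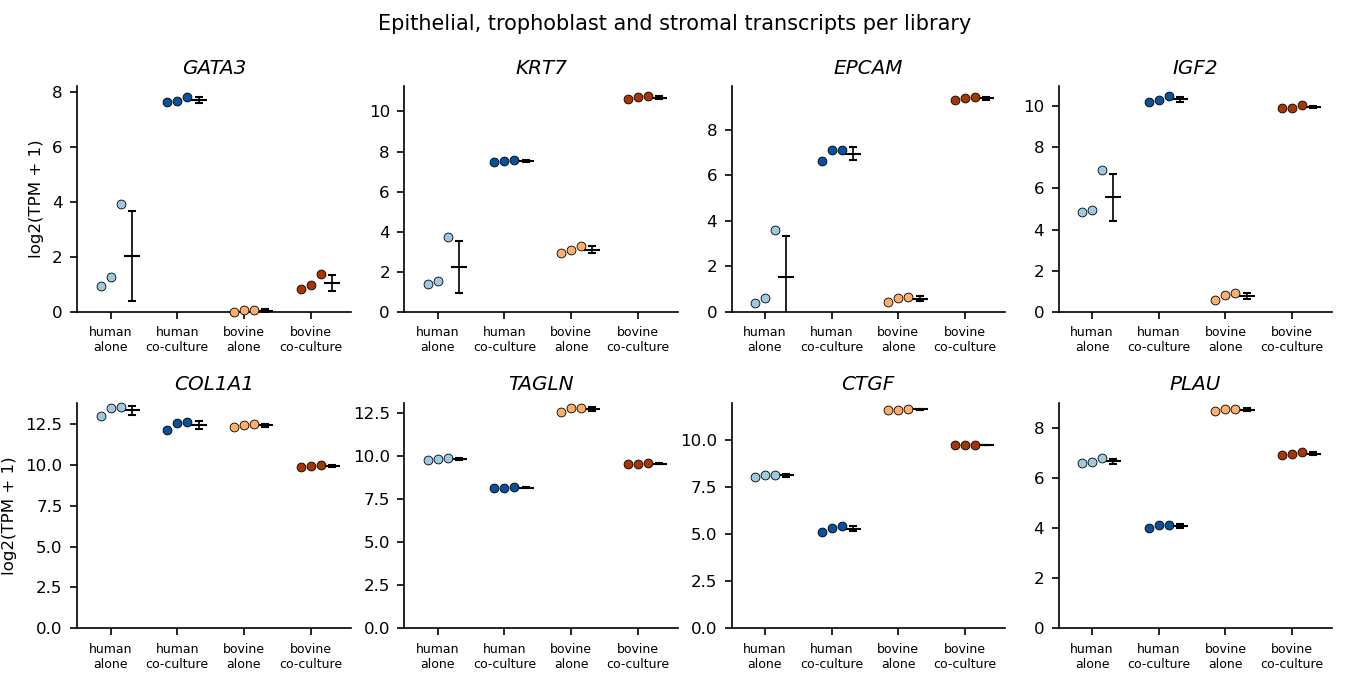
Expression per library as log2(TPM + 1) of 4 genes of trophoblast or epithelium (upper row) and 4 of stroma (lower row) in the 4 groups. Points are libraries in order of value, and the bar beside them is the mean with its SD (n = 3). KRT7, EPCAM and IGF2 were higher in co-culture in both species and GATA3 reached 208 TPM in human co-culture, while the stromal genes were lower in co-culture in both species.

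Genes of the stromal matrix, of contraction and of matrix breakdown fell with them. Of 31 fibrillar matrix and matrix glycoprotein genes, 21 fell and 4 rose in human co-culture (22 and 4 adjusted over the list alone; median -0.91, camera adjusted p = 0.00073; adjusted p = 0.566 with an estimated correlation). Thrombospondin 1, THBS1, went from 6510 ± 303 to 1779 ± 371 TPM. MFAP5 and FBLN2, both of elastic fibres, went the other way, with FBLN2 rising from 31.4 ± 9.62 to 337 ± 53.1 TPM. Matrix proteases fell in 18 of 26 cases and rose in 4 (19 and 4 adjusted over the list alone; median -0.80, adjusted p = 0.000135; adjusted p = 0.465 with an estimated correlation). Urokinase, PLAU, which activates plasminogen, went from 99.9 ± 7.46 to 15.8 ± 0.92 TPM and the collagenase MMP1 from 325 ± 14.1 to 75.6 ± 8.52 TPM. Contractile genes fell in 22 of 25 cases and 1 rose (median -0.86, adjusted p = 1.1e-05; adjusted p = 0.465 with an estimated correlation), with TAGLN at 914 ± 33.4 TPM alone and 286 ± 7.39 TPM in co-culture.

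Targets of the mechanically responsive co-activator YAP fell in 15 of 17 cases and none rose (median -1.24, adjusted p = 1.1e-05; adjusted p = 0.465 with an estimated correlation). CTGF went from 280 ± 13.9 to 38.4 ± 3.77 TPM, ANKRD1 from 12.05 ± 1.81 to 1.15 ± 0.03 TPM and tissue factor, F3, from 290 ± 22.6 to 59.9 ± 6.84 TPM. Integrins and cadherins fell in 16 of 21 cases with 2 rising (median -0.79, adjusted p = 0.000105; adjusted p = 0.465 with an estimated correlation), among them ITGB3, ITGA4 and the hyaluronan receptor CD44 of the same list, at 2330 ± 74.4 TPM alone and 694 ± 54.2 TPM in co-culture. Endometrial stromal markers fell in 14 of 16 cases and none rose (median -0.65, adjusted p = 9.1e-05; adjusted p = 0.465 with an estimated correlation). ANPEP went from 1617 ± 240 to 398 ± 53.0 TPM, MME (CD10) from 1104 ± 80.4 to 404 ± 60.2 TPM and the progesterone receptor, PGR, from 13.5 ± 0.73 to 4.49 ± 0.43 TPM. These falls stood beside the rise of trophoblast and epithelial markers in the same libraries.

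Among secreted and signalling genes of the human cultures, growth factors and their receptors fell in 23 of 32 cases and rose in 6 (median -0.90, adjusted p = 6.5e-05; adjusted p = 0.465 with an estimated correlation). IGF2 was among those that rose, from 58.3 ± 50.7 to 1289 ± 123 TPM (log2 change 4.76, or 5.42 without the human library that held trophoblast transcripts). Immediate early genes fell in 15 of 27 cases and rose in 5 (median -0.59, adjusted p = 0.012; adjusted p = 0.465 with an estimated correlation), with KLF4 and DUSP4 among the risers. Interferon-stimulated genes fell in 16 of 32 cases and rose in 4 (median -0.32, adjusted p = 0.0047; adjusted p = 0.465 with an estimated correlation), with IFIT3 at 34.8 ± 1.25 TPM alone and 8.15 ± 0.66 TPM in co-culture. Decidualization genes, which mark the change of stromal fibroblasts into secretory decidual cells, fell in 12 of 18 cases and rose in 4 (median -0.50, adjusted p = 0.041; adjusted p = 0.465 with an estimated correlation). This call was not past the threshold with median-of-ratios scaling either (adjusted p = 0.0623). Leaving the estimated correlation aside, that was the highest of 4 alternatives, which ranged from 0.0401. The 3 members of that list with the greatest change all rose, namely ERRFI1, FOXO1 and SOX4, of which the transcription factor FOXO1 went from 6.39 ± 0.93 to 27.0 ± 1.03 TPM.

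Genes of the unfolded protein and amino acid response rose in 20 of 25 cases in human co-culture and 2 fell (median 0.95, adjusted p = 0.000205; adjusted p = 0.465 with an estimated correlation). Among them, the lipoprotein receptor VLDLR went from 2.52 ± 3.42 to 81.7 ± 6.17 TPM (log2 change 4.98, or 5.73 without the human library that held trophoblast transcripts), the cystathionine gamma-lyase CTH from 0.97 ± 0.97 to 15.02 ± 1.90 TPM and DDIT4 from 12.8 ± 1.82 to 62.6 ± 6.35 TPM. All 21 tested ribosomal protein genes rose (median 0.85, adjusted p = 2.7e-05; adjusted p = 0.465 with an estimated correlation). The 13 mitochondrially encoded genes made up 4.27 ± 0.67% of TPM alone and 5.55 ± 0.65% in co-culture, and their list was not called (adjusted p = 0.281). Of genes outside the called lists, the angiogenic factor VEGFA went from 13.6 ± 0.86 to 108 ± 8.02 TPM and the prostaglandin E synthase PTGES from 6.02 ± 4.48 to 139 ± 4.51 TPM. The tests of hypoxia and glycolysis genes and of inflammatory cytokine genes, to which these belong, gave adjusted p = 0.372 and 0.101.

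In all, 8469 of 11844 tested genes changed in human co-culture, 4677 higher and 3792 lower (limma), of which 2752 changed by a log2 of at least 1. Groups did not overlap for 75.2% of tested genes, where chance gives 10%. The split between directions depended on scaling, with 55.2% of the called genes higher as reported and 43.9% after quantile normalization, which moved the median of all genes by -0.17.

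The same question was then asked of the bovine cultures. IGF2, a fetal growth factor, went from 0.71 ± 0.19 to 991 ± 49.3 TPM (log2 change 9.19 ± 0.10, adjusted p = 5.0e-10) and the epithelial adhesion protein EPCAM from 0.49 ± 0.11 to 664 ± 26.7 TPM (8.81 ± 0.08, adjusted p = 5.0e-10). LAMB3, a chain of laminin 332 in epithelial basement membranes, went from 0.30 ± 0.07 to 422 ± 20.5 TPM. C11orf86, the chemokine CCL17 and GPRC5A completed the 6 that rose most. The genes that fell most were ALDH1A1, a retinaldehyde dehydrogenase (1063 ± 114 to 37.5 ± 1.79 TPM, -4.78 ± 0.09, adjusted p = 4.2e-09), FAM13C, MFAP5 (179 ± 20.4 to 10.1 ± 1.29 TPM), FHL1, PRKAR2B and BCHE.

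Bovine epithelial markers rose in 12 of 15 cases and 2 fell (median 2.45, camera adjusted p = 3.1e-05; adjusted p = 0.0550 with an estimated correlation). They included the membrane protease ST14, from 0.37 ± 0.28 to 91.1 ± 4.86 TPM, and PAX8. Rows were keyed by human identifiers, so cattle trophoblast genes without a human counterpart could not be tested. The trophoblast list, of 51 genes, had 7 tested in cattle. Of these 4 rose and 2 fell, and the list was not called (camera adjusted p = 0.207). Within it, KRT7 went from 7.57 ± 1.06 to 1661 ± 94.5 TPM and KRT18 from 372 ± 22.7 to 1281 ± 63.0 TPM, while GATA2 fell from 32.4 ± 6.87 to 7.53 ± 0.33 TPM. The co-cultured libraries thus held more epithelial transcripts beside every change given for cattle.

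Fibrillar matrix genes fell in 22 of 27 cases in bovine co-culture and 3 rose (median -2.18, adjusted p = 3.0e-05; adjusted p = 0.0550 with an estimated correlation). MFAP5 changed most, and the adhesion-modulating TNC (34.1 ± 2.17 to 453 ± 10.97 TPM) and COL8A1 (21.8 ± 2.31 to 262 ± 11.2 TPM) rose. Contractile genes fell in 22 of 24 cases and 1 rose (median -1.13, adjusted p = 7.8e-06; adjusted p = 0.0550 with an estimated correlation), with smooth muscle actin, ACTA2, going from 5714 ± 165 to 687 ± 24.9 TPM and TAGLN from 6921 ± 620 to 760 ± 16.7 TPM. Matrix proteases fell in 15 of 20 cases and rose in 4 (median -1.43, adjusted p = 0.0052; adjusted p = 0.128 with an estimated correlation). Cathepsin K, CTSK, went from 1757 ± 105 to 198 ± 11.7 TPM, while tissue plasminogen activator, PLAT, rose from 47.9 ± 0.57 to 1190 ± 27.8 TPM. Protease inhibitors fell in 9 of 11 cases and rose in 2 (median -1.80, adjusted p = 0.011; adjusted p = 0.183 with an estimated correlation), with the metalloprotease inhibitor TIMP3 at 1106 ± 44.7 TPM alone and 172 ± 12.5 TPM in co-culture.

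Sterol synthesis genes rose in 17 of 23 cases in bovine co-culture and 4 fell (median 0.85, adjusted p = 4.9e-05; adjusted p = 0.0550 with an estimated correlation). SQLE, the squalene epoxidase, went from 22.7 ± 1.67 to 181 ± 3.47 TPM, DHCR24 from 7.98 ± 1.15 to 67.1 ± 1.87 TPM and HMGCS1 from 24.5 ± 1.99 to 124 ± 1.06 TPM. Cell cycle genes fell in 27 of 38 cases and rose in 3 (27 and 4 adjusted over the list alone; median -0.53, adjusted p = 0.0096; adjusted p = 0.485 with an estimated correlation), as with cyclin A2, CCNA2, at 74.3 ± 4.85 TPM alone and 30.2 ± 1.97 TPM in co-culture. All 13 mitochondrially encoded genes rose (median 0.61, adjusted p = 0.00023; adjusted p = 0.495 with an estimated correlation), and their share of TPM was 12.9 ± 1.33% alone and 19.5 ± 0.64% in co-culture. Ribosomal protein genes rose in 10 of 16 cases and none fell (median 0.36, adjusted p = 0.0040; adjusted p = 0.491 with an estimated correlation). Outside called lists, the prostaglandin synthase PTGS2 went from 14.4 ± 2.64 to 517 ± 26.2 TPM, the glucose transporter SLC2A1 from 10.1 ± 1.503 to 365 ± 6.67 TPM and the Wnt-pathway factor LEF1 from 0.09 ± 0.08 to 74.2 ± 4.77 TPM.

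In bovine co-culture 8035 of 12058 tested genes changed, 3292 higher and 4743 lower, of which 2787 changed by a log2 of at least 1. Groups did not overlap for 71.8% of tested genes. Of the called genes 41.0% were higher as reported, 51.3% with median-of-ratios scaling and 56.6% with totals that left out mitochondrial and ribosomal protein genes. These scalings moved the median of all genes by 0.12 and 0.19.

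**Figure D2:**
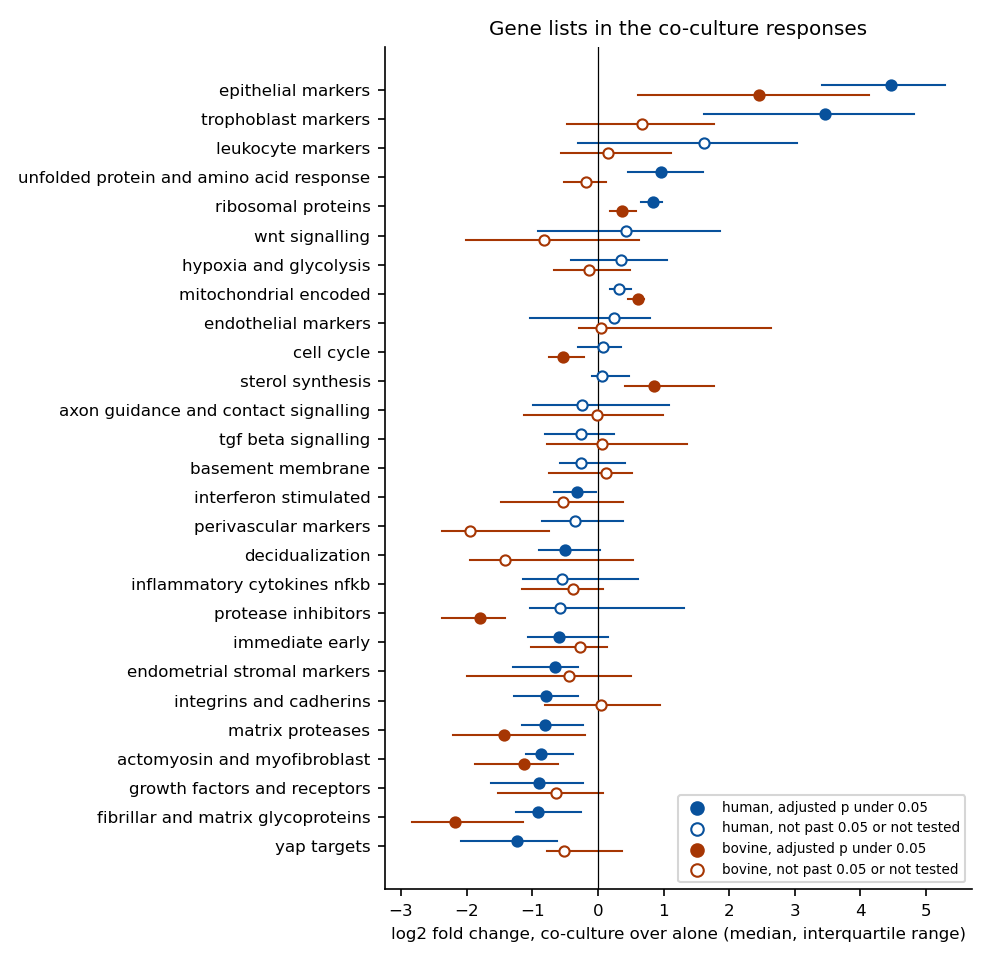
Median log2 fold change of co-culture over culture alone for each of the 27 gene lists in human (blue) and bovine (orange) cultures, with lines for the interquartile range over list members. Filled points passed an adjusted p of 0.05 by camera with a preset correlation. Epithelial markers lie highest in both species, with medians of 4.47 and 2.45, and fibrillar matrix genes lie at -0.91 and -2.18.

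The design next asks whether the 2 species responded differently. Genes of opposite direction led this comparison, which was made on TPM rescaled over the shared genes. No library held trophoblasts alone or sorted stromal cells. A difference of responses may therefore lie in trophoblast RNA, in the stromal cells or in both. MFAP5 rose in human cultures (4.85 ± 3.29 to 65.7 ± 7.42 TPM) and fell in bovine ones (201 ± 22.4 to 11.6 ± 1.45 TPM), a difference of 7.65 ± 0.38 in log2 response (adjusted p = 2.4e-09). The Wnt ligand WNT11 and ROR2, a receptor for Wnt ligands, behaved likewise, with differences of 7.19 ± 0.67 and 7.22 ± 0.75. ROR2 went from 3.18 ± 4.76 to 102 ± 5.30 TPM in human and from 41.7 ± 4.89 to 9.92 ± 0.63 TPM in bovine cultures. ANKRD6 (7.73 ± 0.72), the carbonic anhydrase CA2 (7.47 ± 0.69) and TPD52L1 (7.40 ± 0.47) were the others with a higher human log2 change. Without the human library that held trophoblast transcripts, the differences were 8.14 for ROR2, 8.01 for WNT11, 8.61 for ANKRD6 and 8.29 for CA2. In the opposite sense, transglutaminase 2, TGM2, fell from 342 ± 28.4 to 110 ± 3.87 TPM in human and rose from 0.81 ± 0.11 to 376 ± 7.21 TPM in bovine cultures (-9.33 ± 0.11, adjusted p = 9.4e-15). GPRC5A (-10.13 ± 0.14), LAMB3 (-9.71 ± 0.15) and the semaphorin receptor NRP1 (-7.59 ± 0.19) fell in human and rose in bovine cultures. CCL17 and LUZP2 reached 352 ± 16.9 and 238 ± 9.39 TPM in bovine co-culture. CCL17 was listed at 0 in every human library alone, and LUZP2 at 0 in every bovine library alone, so no fold is given for them.

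**Figure D3:**
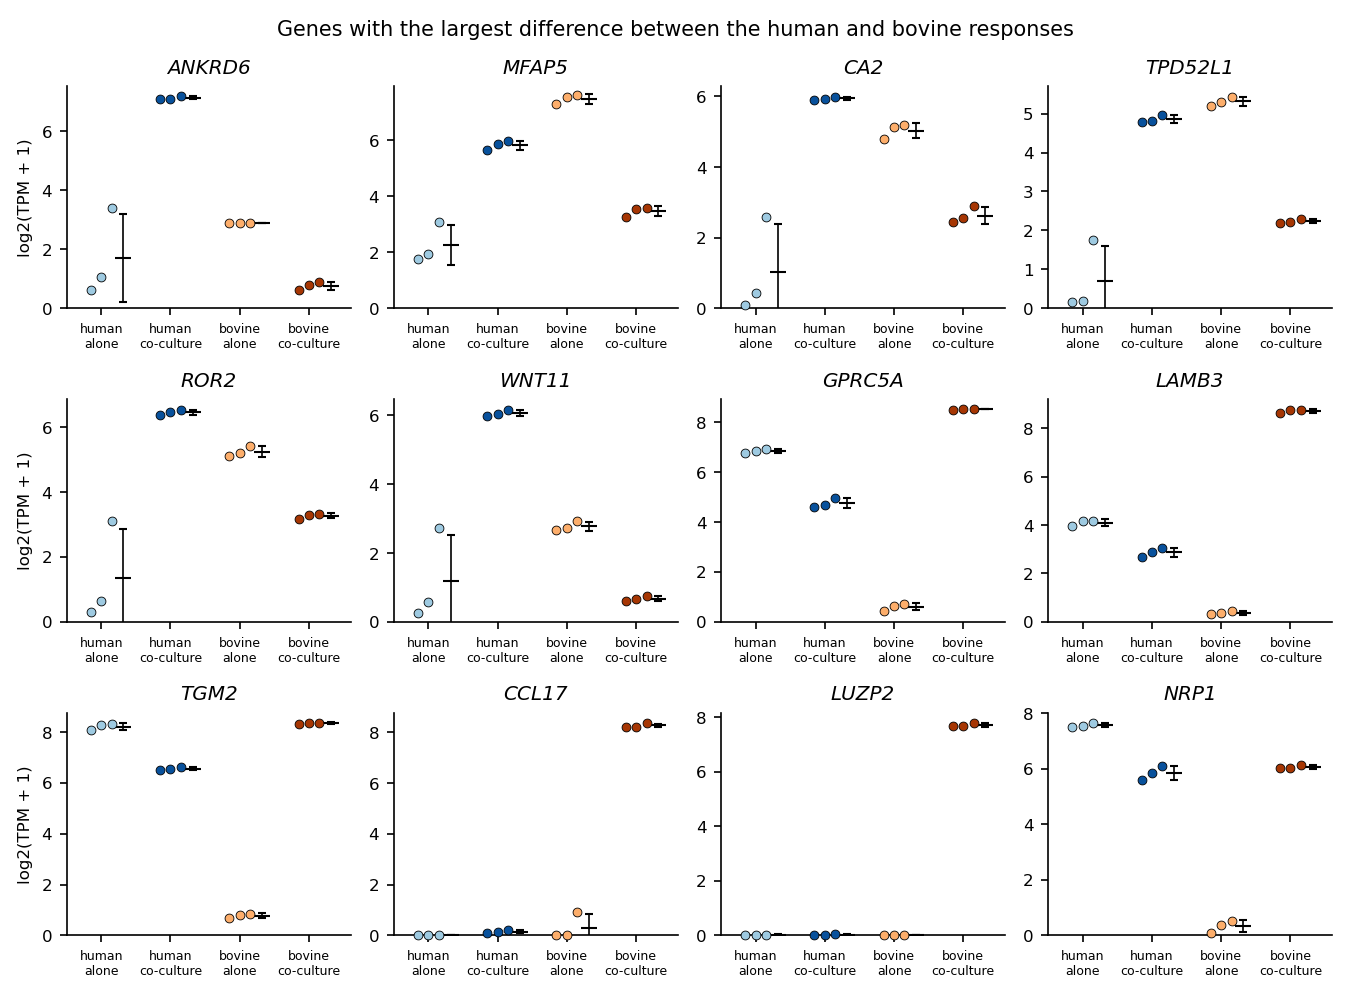
Expression per library as log2(TPM + 1), from TPM as deposited, of the 12 genes with the largest difference between the human and bovine responses. Points are libraries in order of value, with the mean and SD beside them (n = 3). The first 6 genes were higher in co-culture in human libraries and lower in bovine ones, and the last 6 were higher in bovine co-culture.

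By list, the log2 change of trophoblast markers was higher in human than in bovine cultures in 12 of 15 cases and lower in 1 (median difference 2.96, camera adjusted p = 0.0066; adjusted p = 0.815 with an estimated correlation). Of these 15 markers 8 were too low to be tested in the bovine response, so the sign of their difference mostly follows the human response alone. Cattle trophoblast genes without a human identifier were not among the 15. Over the 7 tested in both species, 5 had a higher and 1 a lower log2 change in human cultures (median 2.12). CYP19A1 and CGA were listed at 0 in every bovine library alone and were at 0.01 ± 0.01 and 0.32 ± 0.02 TPM in bovine co-culture. GATA2 rose in human cultures (27.5 ± 7.96 to 315 ± 19.9 TPM) and fell in bovine ones (36.3 ± 7.79 to 8.62 ± 0.41 TPM). Unfolded protein and amino acid response genes had a higher log2 change in human cultures in 21 of 25 cases and none a lower one (median 0.93, adjusted p = 0.00046; adjusted p = 0.338 with an estimated correlation). Within this list, CTH rose in human and fell in bovine cultures (5.35 ± 0.35).

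Sterol synthesis genes had a lower log2 change in human than in bovine cultures in 17 of 23 cases and a higher one in 4 (18 and 4 adjusted over the list alone; median -0.95, adjusted p = 0.00032; adjusted p = 0.153 with an estimated correlation), with DHCR24 at -4.01 ± 0.14 and SQLE at -2.73 ± 0.10. YAP targets had a lower log2 change in human cultures in 11 of 16 cases and a higher one in 4 (median -0.78, adjusted p = 0.0061, or adjusted p = 0.338 with an estimated correlation). In the bovine response this list was not called, with 10 of 16 falling and 5 rising (median -0.51, camera adjusted p = 0.452). Tissue factor, F3, fell from 331 ± 26.6 to 70.2 ± 7.99 TPM in human and rose from 265 ± 10.8 to 802 ± 22.4 TPM in bovine cultures. Integrins and cadherins (log2 change lower in human cultures in 13 of 21 cases and higher in 5, or 13 and 6 adjusted over the list alone; median -0.56, adjusted p = 0.019; adjusted p = 0.815 with an estimated correlation) were not past the threshold with median-of-ratios scaling either (adjusted p = 0.0527). Leaving the estimated correlation aside, that was the highest of 4 alternatives, which ranged from 0.0172. TGF-beta signalling genes had a lower log2 change in human cultures in 15 of 28 cases and a higher one in 6 (15 and 7 adjusted over the list alone; median -0.52, adjusted p = 0.014; adjusted p = 0.784 with an estimated correlation). INHBA, a subunit of activin, fell from 109 ± 4.96 to 24.9 ± 2.57 TPM in human and went from 58.2 ± 7.02 to 118 ± 9.003 TPM in bovine cultures.

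The response differed for 8262 of 11835 shared genes tested, with a higher human log2 change in 5098 and a lower one in 3164, and 3981 differed by a log2 of at least 1. Of these called genes 61.7% had the higher log2 change in human cultures as reported, 48.3% with median-of-ratios scaling, 50.2% after quantile normalization and 54.7% without mitochondrial and ribosomal protein genes. Those scalings moved the median difference by -0.24, -0.21 and -0.13.

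Across 9958 shared genes tested in both species, the human and bovine log2 changes had a Spearman correlation of 0.154 and a Pearson correlation of 0.192. Genes are not independent replicates, so no p-value is given for these. Of 4748 genes called in both responses, 2697 moved the same way and 2051 opposite ways (43.2%). Directions depend on scaling, which was not varied for these counts or for the overlaps below. In bovine cultures the higher share of called genes went from 41.0% to 56.6% without mitochondrial and ribosomal protein genes. In human cultures it went from 55.2% to 43.9% after quantile normalization. Genes that rose in both numbered 1175 where independent lists would share 967 (odds ratio 1.58, 95% interval 1.44 to 1.74, Fisher's exact p = 1.1e-22), and genes that fell in both numbered 1522 against 1296 (odds ratio 1.53, 95% interval 1.41 to 1.67, Fisher's exact p = 7.6e-23). The responses share no libraries, but Fisher's test and its intervals also treat genes as independent, so they overstate the certainty of this overlap.

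**Figure D4:**
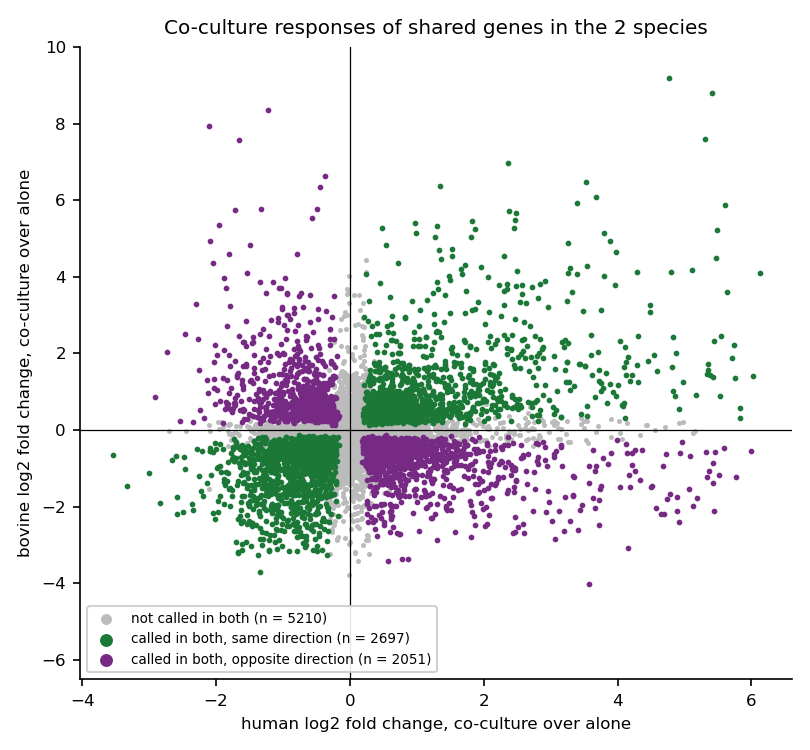
Log2 fold change of co-culture over culture alone in bovine (vertical) against human (horizontal) cultures for 9958 shared genes, 1 point per gene. Green points are 2697 genes called in both species in the same direction, purple points are 2051 called in opposite directions and grey points are the other 5210. Directions are those of TPM as deposited, and other scalings were not tried for these counts. The cloud fills all 4 quadrants, with a Spearman correlation of 0.154.

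The stromal cultures of the 2 species also differed without trophoblasts. Species, genome annotation, transcript models and culture differ together in this comparison and cannot be separated. Higher in human cultures were the peptidases ANPEP (1847 ± 267 against 0.01 ± 0.02 TPM, log2 difference 10.82 ± 0.12, adjusted p = 3.4e-16) and MME (1262 ± 97.7 against 0.12 ± 0.05 TPM), the oxytocin receptor OXTR (875 ± 62.2 against 0.15 ± 0.06 TPM), the BMP antagonist GREM1 (2023 ± 163 against 1.92 ± 0.99 TPM), SPOCK1 and THBS2. MGLL stood at 1002 ± 62.2 TPM in human cultures and was listed at 0 in every bovine library alone. RPN1, part of the oligosaccharyltransferase that cells in general need, was at 742 ± 36.9 TPM against 0.15 ± 0.06 TPM.

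Higher in bovine cultures were UPK1B, a uroplakin (1813 ± 45.4 against 0.08 ± 0.03 TPM, -10.71 ± 0.07, adjusted p = 6.3e-18), ALDH1A1 (1192 ± 125 against 0.06 ± 0.06 TPM), the cytokine IL18 (1167 ± 174 against 0.69 ± 0.05 TPM), mesothelin, MSLN (594 ± 57.2 against 0.12 ± 0.06 TPM), LRRN4 and the matricellular protein POSTN (1322 ± 283 against 1.54 ± 0.32 TPM). IGFBP2, which binds insulin-like growth factors, stood at 2660 ± 459 TPM and was listed at 0 in every human library alone. PGAM4, whose human gene is a near copy of the glycolytic gene PGAM1, was at 1184 ± 35.3 against 0.06 ± 0.06 TPM, and its value is uncertain because reads of such copies can be split or assigned to the other.

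Cell cycle genes were higher in human cultures alone in 30 of 38 cases and lower in 2 (median 1.08, camera adjusted p = 0.0012; adjusted p = 0.727 with an estimated correlation), with topoisomerase TOP2A at 742 ± 108 against 64.0 ± 18.3 TPM. Sterol synthesis genes were higher in 17 of 23 cases and lower in 5 (median 1.43, adjusted p = 0.027; adjusted p = 0.727 with an estimated correlation). Lower in human cultures were genes of the unfolded protein and amino acid response in 20 of 25 cases, with 3 higher (median -0.93, adjusted p = 0.0052; adjusted p = 0.727 with an estimated correlation), as with asparagine synthetase, ASNS, at 9.73 ± 0.57 against 308 ± 16.1 TPM. Mitochondrially encoded genes were lower in 12 of 13 cases and none higher (median -1.46, adjusted p = 0.0072; adjusted p = 0.906 with an estimated correlation), although 2 were higher after quantile normalization. Ribosomal protein genes were lower in 15 of 16 cases and 1 was higher (median -1.84, adjusted p = 0.00064; adjusted p = 0.727 with an estimated correlation). In total 10088 of 11835 genes differed, 5302 higher and 4786 lower in human cultures, and 52.6% of the called genes were higher. Leaving mitochondrial and ribosomal protein genes out of the totals moved the median by -0.16 and turned the majority, with 4809 genes higher and 5359 lower (47.3% higher).

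In co-culture 10497 of the 11835 genes differed between species, 6170 higher and 4327 lower in human libraries. The higher share of called genes was 58.8% as reported, 49.9% both with median-of-ratios scaling and after quantile normalization, and 50.3% without mitochondrial and ribosomal protein genes, which moved the median by -0.36, -0.35 and -0.33. Cell cycle genes were higher in human libraries in 33 of 38 cases and lower in 2 (median 1.45, adjusted p = 0.00038; adjusted p = 0.973 with an estimated correlation). Mitochondrially encoded genes were lower in all 13 cases (median -1.90, adjusted p = 0.00084; adjusted p = 0.973 with an estimated correlation), with 2 higher after quantile normalization, and ribosomal protein genes were lower in 13 of 16 cases with 1 higher (median -1.23, adjusted p = 0.0015; adjusted p = 0.973 with an estimated correlation). Sterol synthesis genes (12 of 23 higher, 7 lower) and unfolded protein and amino acid response genes (14 of 25 higher, 10 lower) were not called in co-culture (camera adjusted p = 0.935 for both). Without trophoblasts both lists differed in the sense opposite to their difference of responses, which uses the same libraries alone. These 2 calls are therefore not independent. A total of 8016 genes differed in the same direction alone and in co-culture and 1072 in opposite directions. The differences of ANPEP, MME, OXTR, MSLN, UPK1B and POSTN kept their direction in co-culture, with log2 differences of 8.83, 6.31, 6.96, -7.65, -8.49 and -5.45.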

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

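The tests of other cells' RNA, of bovine gene models and of other splits of the libraries were chosen after the results were seen. The difference of responses between species was a planned test.

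The response to co-culture differed between human and bovine cultures for 8262 genes by a test of the difference itself. The genes with the largest differences, as human minus bovine log2 response, were ANKRD6 (7.73), MFAP5 (7.65), CA2 (7.47), TPD52L1 (7.395), ROR2 (7.22), WNT11 (7.19), GPRC5A (-10.13), LAMB3 (-9.71), TGM2 (-9.33) and NRP1 (-7.59). The fitted values of CCL17 (-7.97) and LUZP2 (-7.90) depend on the pseudocount, since each is listed at 0 in every library of a group. List medians that differed were -0.52 for TGF-beta signalling, -0.78 for YAP targets, -0.56 for integrins and cadherins, -0.95 for sterol synthesis, 0.93 for the unfolded protein and amino acid response and 2.96 for trophoblast markers, of which 8 of 15 were too low to be tested in the bovine response. With an estimated correlation none of these 6 lists passed (adjusted p = 0.784, 0.338, 0.815, 0.153, 0.338 and 0.815 in this order), and integrins and cadherins did not pass with median-of-ratios scaling either (adjusted p = 0.0527). The 10 human and 10 bovine splits of 3 against 3 made 100 combinations. Only 1, the real one, gave as many genes, and the highest other gave 3866. The 81 combinations with the real grouping of neither species gave at most 0 genes. Other splits mix libraries alone with co-cultured ones, which widens the spread within groups, and none exchanged the labels of 1 species. They therefore cannot decide whether the responses differ between species. For the 4 other counts, 10 splits of 3 against 3 are too few for a share under 0.05. The real counts were 8469 (human response), 8035 (bovine response), 10088 (species alone) and 10497 (species in co-culture), in each case reached by 1 split, the real one, and the highest other split gave 0 genes at the threshold for each.

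The first pattern is the rise of trophoblast and epithelial transcripts with a fall of stromal ones. In bovine cultures the trophoblast markers (7 of 51 tested, of which 4 rose and 2 fell) and the endometrial stromal markers (9 of 17 fell, 6 rose) were not called (camera adjusted p = 0.207 and 0.550). Of the trophoblast markers tested in human cultures 87% rose, and of the epithelial markers tested in bovine cultures 80% rose. These shares restate the pattern, so they do not test whether trophoblast RNA in the co-cultured libraries is its source. Induction of these genes in the stromal cells themselves stays open, because there were 0 libraries of trophoblasts alone or of sorted stromal cells. Dilution of unchanged stromal RNA and a true fall cannot be told apart for the same reason. Among genes above 50 TPM alone, the lowest co-culture level was 7.39% of that alone in human cultures (BMPER) and 3.53% in bovine ones (ALDH1A1). Each is the value of 1 gene, and the 1st percentile was 23.3% in human and 11.63% in bovine cultures. If no stromal gene had changed, the lowest levels would be upper bounds on the stromal share. Against that, the stromal genes COL3A1, DCN, LUM, PDGFRA and COL1A1 stood at 117.6%, 83.6%, 83.5%, 69.8% and 53.1% of their level alone in human co-culture, and at 25.8%, 26.6%, 16.7%, 51.7% and 17.5% in bovine co-culture. Lower levels were those of MMP2, at 43.0% in human and 13.5% in bovine co-culture, and of TERT, at 22.1% in human co-culture. If those bounds hold, dilution alone would need trophoblasts to supply most of the transcripts of these genes, and trophoblast levels were not measured. True falls of the lowest genes would void the bounds.

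The second pattern is the presence of co-culture transcripts in 1 of the 3 human libraries cultured alone. In that library 99.6% of the genes that rose over 8-fold against the other 2 were above both of them. Its median excess was 6.75% of the co-culture excess (quartiles 5.63% and 7.86%), against -0.153% between the other 2, so a small share of RNA from co-culture or trophoblasts is consistent with the data. An exchange of labels with a co-cultured library would need an excess of 50% or more and is excluded by the 6.75%. No biological explanation was tested.

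The third pattern is the near absence in bovine libraries of genes that cells in general use, such as RPN1. Of 39 ribosomal protein genes above 50 TPM in every human library, 2 lay under 1% of their human level in cattle (RPL31 at 426 against 0.0585 TPM and RPL36AL at 154 against 0.357 TPM), compared with 45 of 3284 genes overall (Fisher's exact p = 0.0989). Gene models or ortholog assignment of the bovine genome may leave such genes out. For this explanation, 2 is fewer than the 3 that the test required. The test counted only shared genes, which have a value above 0 in cattle, so genes left out entirely could not enter it. It therefore cannot decide the question. Apart from it, 37 identifiers with a mean human TPM above 20 were listed at 0 in every bovine library. There were 0 bovine annotations in which to look such transcripts up. A truly lower bovine level cannot be told apart from faults of gene models or ortholog assignment.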

How the results depend on the processing

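The filter of a mean of 1 TPM in each species and the list tests without 1 human library were chosen after the results were seen. A log2 change of at least 1 left 2752 (human response), 2787 (bovine response), 3981 (difference), 6318 (species alone) and 6834 genes (species in co-culture). Of the 37 list calls, 0 passed with camera's estimated correlation, and 35 passed with median-of-ratios scaling. The former also lowers the degrees of freedom, so the loss of all calls does not measure gene correlation alone. Leave-one-out counts ranged from 7070 to 8822, 6515 to 8525, 7631 to 8452, 9724 to 10012 and 10061 to 10137 in the same order, and the correlation of responses from 0.137 to 0.170. In the difference, MT-ND5, MT-ND4L and MT-ND3 changed sign after quantile normalization (0.132, 0.149 and 0.212), and the cause was not tested. Same-numbered libraries did not pair consistently (r of deviations -0.31, -0.10 and 0.06 in human, 0.34, 0.32 and -0.002 in bovine cultures). A replicate block gave 7783, 8377, 8047, 10033 and 10453 genes, kept all 37 list calls and ended the calls of MT-CYB in the human response (adjusted p = 0.0553) and MT-ND3 in the difference (0.101). Across all alternatives, results for single named genes and lists fell short of the threshold in 56 cases, 37 of them with the estimated correlation, and newly passed it in 2, both with median-of-ratios scaling. The deposited TPM hold no read depth, so what depth limits could not be assessed.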

Other observations

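The imprinted and oncofetal genes and the TERT values were chosen after results were seen. The mesothelial test used genes whose values had not been seen when its prediction was written.

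Some signalling and matrix genes moved in opposite directions in the 2 species. The basement membrane gene LAMB1 rose by a log2 of 1.18 in human and fell by 1.70 in bovine cultures, and complement C3 rose by 2.60 and fell by 2.69. The contact signalling receptor EPHB3 rose by 2.47 in human and fell by 2.65 in bovine cultures. TERT, the catalytic subunit of telomerase, stood at 504 ± 49.7 TPM in human cultures alone and 111 ± 11.3 TPM in human co-culture. In bovine libraries TERT did not exceed 0.088 TPM alone and 1.18 TPM in co-culture. The source of the high human level was not tested, so it is no evidence of native telomerase expression.

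Mesothelial markers were common among genes higher in bovine than in human culture alone, such as MSLN, UPK1B and LRRN4. The hypothesis of mesothelium-like cells in the bovine cultures was tested on 12 further markers, of which 91.67% were higher in bovine cultures (11 of 12, median log2 difference of human minus bovine -3.68), including WT1 at 128 and PDPN at 259 TPM. Over all 11835 genes tested, 4786 were higher in bovine cultures. Of the 16 further markers listed, 12 passed the filter in the bovine response and 6 in the human one. Markers that passed only through bovine libraries were nearly bound to read higher there, so this share cannot decide the question. Stromal cells may also express WT1 and PDPN, KRT19 is also in the trophoblast list, and species differs together with annotation and culture. In bovine co-culture 7 of these 12 markers fell and 2 rose (median -1.86).

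A list of imprinted and oncofetal genes was drawn up after IGF2 was seen to rise most in bovine co-culture. With the genes seen beforehand, 6 of 11 tested members rose and 2 fell in bovine co-culture. Of the 8 not seen beforehand, 3 rose and 2 fell (median log2 change 0.07), and in human co-culture 5 of 9 not seen beforehand rose and 2 fell (median 0.27). The members not seen beforehand did not bear out the hypothesis that such genes rise as a class in bovine co-culture.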
